A study of Homo sapiens with 15 samples.

How the data were processed

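RNA was sequenced from H1299 cells with Illumina libraries made from total RNA, per the labels' protocols. Trimmomatic 0.39, STAR 2.7.10a and the genome build GRCh38 are named in the submitters' processing notes. The counting tool, the gene annotation, the strand setting and any selection of polyadenylated RNA are not given in the sources used here. The deposited files hold whole-number counts of reads per gene that the authors did not normalise, 1 library per file, with 61552 Ensembl gene IDs in each; unit and lack of scaling were read from the values themselves. Symbols were found for 61399 IDs in a table of gene names, and 58352 IDs were present in GENCODE release 29, from which the positions printed here on GRCh38 were taken. Every row was named by a gene, so none was left out of the library sizes.

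Groups were taken from the sample titles: WT and Ctrl in 2023, and p53, LLPSEp53_1 and LLPSEp53_2 in 2022, with 3 libraries each. The columns in the LLPSEp53_1 files carry no construct number, so their assignment to that construct rests on sample titles and file names. The labels state the year and that p53 replicate 2 belonged to a different batch. They do not state that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom from 7.46 to 128), so each counted as 1 replicate.

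Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr, and the quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05. WT and Ctrl were fitted on their 6 libraries. The 9 libraries of 2022 were fitted together by group with a term for the other batch; since p53 replicate 2 is alone in that batch it does not enter any difference between groups, and p53 was represented by 2 libraries. Differences are log2 fold changes with their standard errors, and CPM values are library-scaled counts, computed by edgeR's cpm function after TMM scaling, with the mean and SD over libraries. Every adjusted p of a single gene comes from edgeR.

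Genes induced or repressed by WT were those past the threshold with at least 2-fold change in the 2023 libraries. These 2 sets and 19 fixed gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Camera was run again with an estimated correlation. Set p values printed in the report are those with an estimated correlation unless fry is named, and the alternatives used the preset one. Fry in limma was run beside camera and does not set a list against other genes. Its directional test asks whether the members of a list move in a shared direction. Its mixed test asks whether they move in either direction. Fry p values are those of the directional test unless the mixed test is named. Lists with fewer than 3 measured genes were not tested. The lists were p53 targets in growth arrest, apoptosis, DNA repair, feedback, metabolism and autophagy, and others, G1/S genes, G2/M genes, interferon response, NF-kB targets, heat shock genes, the unfolded protein and integrated stress response, NRF2 targets, sterol synthesis, epithelial-mesenchymal genes, ribosome biogenesis, markers of other cell types, mitochondrially encoded mRNAs and replication-dependent histones. CDKN1A and MDM2 are always named. Other genes named are the 10 largest rises and the 10 largest falls of each comparison among called genes with a symbol, an average log2 CPM of at least 2 and groups whose libraries do not overlap (p53 replicate 2 left aside), and up to 4 members of each list with the smallest adjusted p. FGFR3, KCNJ12 and ARC are followed beyond the comparison that named them. Certain results are not reported here. Groups, comparisons, lists, the naming rule and all alternatives except 2 were fixed before the data were examined.

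The alternatives were DESeq2 1.42.0, relative log expression and upper-quartile scaling, no filter on low counts, each library left out in turn, the replicate number as a block, no batch term, only the groups compared in the fit, a 2-fold minimum, and other definitions of the induced and repressed sets. Offsets that remove each library's trend with the GC content or the length of genes, taken from GENCODE transcripts, were added after seeing the data; 98.2% of the genes over a log2 CPM of 2 had a GC value in the 2023 fit and 98.0% in the 2022 fit.

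Total counts of 13535397 to 19228748 per library put the limit that a count of 0 allows, taken as 3 counts, at 0.156 to 0.222 CPM. The steps were tested on simulated counts drawn from the real means, library sizes and spread, with a set of genes changed by a known fold. For WT against Ctrl (15740 genes), edgeR recovered 52.3% of genes changed 1.5-fold, 83.1% of those changed 2-fold and 96.8% of those changed 4-fold. For LLPSEp53_1 against p53 (16897 genes) the shares were 6.1%, 65.7% and 84.1%, and for LLPSEp53_2 against p53 (16897 genes) 10.8%, 53.8% and 89.1%. False calls made up 5.1%, 8.2% and 8.3% of calls by edgeR, and 4.6%, 13.6% and 8.1% by DESeq2, in the same order. Figures were drawn with matplotlib.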

Results

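RNA-seq was used to measure gene expression in H1299 cells, a human lung cancer line known to lack functional p53, after overexpression of p53 constructs. The series held 15 libraries in 5 groups of 3. In the data of 2023, cells carried a control vector (Ctrl) or wild-type p53 (WT). In the data of 2022, cells carried p53, LLPSEp53_1 or LLPSEp53_2. The 2 LLPSEp53 constructs are named here as in the labels, and the series title places them in a study of how the tendency of p53 to undergo liquid-liquid phase separation bears on its activity. Total counts ranged from 16208538 to 19228748 per library in 2023 and from 13535397 to 16438272 in 2022. No vector control was among the libraries of 2022, and p53 replicate 2 was collected in a different batch from the other libraries of that year, per the labels. The 2022 comparisons therefore carried a term for that batch, so that p53 replicates 1 and 3 set the p53 level.

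The comparison of WT with Ctrl asked which genes respond to p53. Known p53 targets rose with WT. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (ENSG00000124762; GRCh38 chromosome 6, 36676460 to 36687339, plus strand), rose 3.13-fold, from 242 ± 10.4 to 758 ± 37.9 library-scaled counts (CPM; SD, n = 3 each; adjusted p = 5.8e-09). MDM2, the ubiquitin ligase that degrades p53 (ENSG00000135679; chromosome 12, 68808176 to 68850686, plus strand), rose 4.61-fold, from 58.8 ± 2.003 to 271 ± 26.5 CPM (SD, n = 3 each; adjusted p = 4.95e-11). In all, 665 of 16156 tested genes changed, 524 higher and 141 lower in WT. At least 2-fold changes were seen for 280 of the rises but only 5 of the falls.

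Steep rises among genes with an average log2 CPM of at least 2 were those of the neuronal vesicle gene NSG1 at 57.3-fold, the transcriptional repressor gene HES2 at 53.9-fold and the axon guidance gene DRAXIN at 40.6-fold. BTG2, an antiproliferative gene, rose 15.6-fold, FAM13C 15.1-fold, DPYSL4 14.6-fold, and TP53I11 8.76-fold. The potassium channel gene KCNJ12 rose 8.78-fold, from 3.10 ± 0.95 to 27.4 ± 4.10 CPM (SD, n = 3 each), and FGFR3, a growth factor receptor gene, rose 7.71-fold, from 5.30 ± 0.57 to 40.8 ± 3.69 CPM (SD, n = 3 each). Falls were smaller. EGR4 was 2.36-fold lower, EGR1 2.22-fold lower and FOSB 1.79-fold lower, all 3 of them immediate early transcription factor genes, and EGR1 went from 332 ± 47.8 to 149 ± 32.5 CPM (SD, n = 3 each). The other falls named by the rule were MISP at 2.25-fold, ZNF668 and the phosphatase gene DUSP8 at 1.69-fold each, CYP1A1 at 1.68-fold, the histone gene H4C8 at 1.67-fold and TNFRSF8 at 1.66-fold. HOXC-AS2 was 1.72-fold lower, but it is antisense to HOXC genes and the strand setting of the counting is not known.

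All 6 lists of p53 targets fixed beforehand rose as sets, and each call held with an estimated correlation between genes. In the apoptosis list, 15 of 17 measured members rose (17 adjusted over the list alone) with a median log2 change of 0.65, among them TP53INP1 at 3.86-fold, APAF1 at 3.44-fold, TP53I3 at 2.84-fold and BBC3 at 1.81-fold. In the growth arrest list, 11 of 17 rose (14 adjusted over the list alone, median 0.82), including SUSD6 at 3.24-fold and GDF15 at 2.79-fold. The DNA repair list had 5 of 8 members higher (5 adjusted over the list alone, median 0.53), with RRM2B at 2.08-fold, POLH at 2.07-fold, DDB2 at 1.91-fold and PCNA at 1.47-fold. The feedback list had 3 of 7 higher (4 adjusted over the list alone, median 0.29), namely MDM2, PPM1D at 1.76-fold and PLK3 at 1.65-fold. In the metabolism and autophagy list, 9 of 16 rose (10 adjusted over the list alone, median 0.50), with SESN1 at 3.90-fold, FDXR at 3.33-fold, PANK1 at 3.28-fold and TIGAR at 3.05-fold. In the list of other targets, 23 of 51 rose (27 higher and 1 lower adjusted over the list alone, median 0.47), with CYFIP2 at 3.60-fold and RPS27L at 2.10-fold. INPP5D of the same list had 0 counts in the Ctrl libraries and stood at 2.16 ± 0.42 CPM in WT (SD, n = 3), so no fold is given. The camera adjusted p with an estimated correlation was 0.0028 for apoptosis, 0.0044 each for growth arrest, metabolism and autophagy, and other targets, 0.025 for feedback and 0.027 for DNA repair.

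Among the lists of other processes, none held with an estimated correlation. Fry gave them adjusted p of 0.012 for NF-kB targets and for replication-dependent histones and 0.038 for heat shock genes. Its adjusted p was 0.54 or more for the rest. Of that rest, fry's mixed test gave adjusted p of 7.4e-04 for epithelial-mesenchymal genes and 0.014 for the stress response list. It gave 0.072 or more for the others. The NF-kB list had 4 of 15 members lower (7 adjusted over the list alone, median log2 change -0.31, camera adjusted p = 0.17 with an estimated correlation): TRAF1 at 1.43-fold, NFKBIA at 1.43-fold, NFKB2 at 1.36-fold and TNFAIP3 at 1.34-fold, of which NFKBIA and TNFAIP3 encode inhibitors of the pathway. Replication-dependent histones had 1 of 15 lower, H4C8 (1 adjusted over the list alone, median -0.29, adjusted p = 0.17 with an estimated correlation). The interferon list had a median of -0.42 (adjusted p = 0.66 with an estimated correlation). Of its 28 members, 0 were called by edgeR or DESeq2, 0 adjusted over the list alone and 8 lower at unadjusted p under 0.05. G1/S genes had a median of -0.09 (adjusted p = 0.76 with an estimated correlation). Of 32 measured, 0 were called by edgeR or DESeq2 and 0 adjusted over the list alone, with 6 lower and 1 higher at unadjusted p under 0.05. Heat shock genes had 1 of 15 higher (1 adjusted over the list alone, median 0.09, adjusted p = 0.30 with an estimated correlation), HSPA6, whose close copy HSPA7 can share reads. Mitochondrially encoded mRNAs had a median of 0.35 (adjusted p = 0.66 with an estimated correlation). Of 13 measured, 0 were called by edgeR or DESeq2, 0 adjusted over the list alone and 1 higher at unadjusted p under 0.05. All mitochondrially encoded genes, ribosomal and transfer RNA genes included, took 0.68% of counts in Ctrl replicate 1 against 1.564% and 1.604% in the other Ctrl libraries. Without Ctrl replicate 1 the median of the mRNA list was -0.05.

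The remaining lists gave no set call in WT against Ctrl. G2/M genes had 1 of 33 lower, CDC25B (0 adjusted over the list alone), with a median log2 change of 0.01 and a mean of the opposite sign. In the unfolded protein and integrated stress response list ATF3 was the 1 of 20 members called, 1.41-fold higher (2 higher and 2 lower adjusted over the list alone). OSGIN1 was the 1 of 17 NRF2 targets called, 1.51-fold lower (1 adjusted over the list alone), and ACTA2 the 1 of 19 epithelial-mesenchymal genes, 2.07-fold higher (1 adjusted over the list alone). Of 19 sterol synthesis genes and 20 ribosome biogenesis genes, 0 were called by edgeR or DESeq2 and 0 adjusted over each list alone. At unadjusted p under 0.05, 2 sterol genes were higher and 3 lower, and 6 ribosome biogenesis genes were lower. Of the markers of other cell types, 2 passed the count filter, VWF and PECAM1, neither above 1.63 CPM in any library.

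These counts came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 665 genes had libraries of WT and Ctrl that did not overlap, as did 22.4% of all tested genes where chance gives 10%. The genes that fell were rich in GC (median 61.6% against 49.8% for all genes), and with each library's GC trend removed, a correction added after seeing the data, 534 genes were higher and 31 lower. The excess of rises over falls was unstable. Leaving out Ctrl replicate 2 gave 1381 genes, 723 higher and 658 lower, and the replicate number as a block gave 1645, 894 higher and 751 lower. Leaving out WT replicate 1 gave 356 genes, 321 higher and 35 lower, and Ctrl replicate 3 369, 338 higher and 31 lower.

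The comparison of LLPSEp53_1 with p53 asked how that construct differs in activity. Most called differences were falls: 155 of 17459 tested genes changed, 146 lower and 9 higher with LLPSEp53_1. Genes that WT had induced at least 2-fold in the separate libraries of 2023 lay below their level with p53, with a median log2 change of -0.35 (quartiles -0.78 and 0.04) against 0.00 for all other genes. Of 269 such genes measured, 195 were below 0, 42 were called lower and 4 higher (91 lower and 13 higher adjusted over the list alone). These counts were unstable: 11 of the set were called lower without p53 replicate 1, 6 without LLPSEp53_1 replicate 2, 26 without LLPSEp53_2 replicate 2 and 16 with the replicate number as a block, with 0 higher by edgeR in each. Without LLPSEp53_1 replicate 1, 57 were lower and 8 higher. Without p53 replicate 3, 0 were called by edgeR, with 88 lower and 14 higher at unadjusted p under 0.05 and 17 lower and 2 higher by DESeq2. FGFR3, named above among the rises with WT, was lower by a log2 change of -0.76 ± 0.15 (SE, adjusted p = 0.0337). Named beside it but not called (log2 change) were NSG1 (-0.53), HES2 (-0.38), DRAXIN (-0.32), BTG2 (-0.24), FAM13C (0.01), DPYSL4 (-0.36), TP53I11 (-0.46) and KCNJ12 (-0.46). CDKN1A did not pass the test, at 424 ± 26.1 CPM (SD, n = 3) against 285 ± 1.46 CPM with p53 (SD, n = 2; log2 difference 0.57; adjusted p = 0.085), and neither did MDM2, at 196 ± 40.2 CPM (SD, n = 3) against 183 ± 26.0 CPM (SD, n = 2; adjusted p = 0.849).

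The steepest falls with LLPSEp53_1 named here are those of genes with an average log2 CPM of at least 2; some genes of lower level fell further. The neuronal RNA-binding protein gene ELAVL3 was 12.8-fold lower, from 7.27 ± 0.34 (SD, n = 2) to 0.57 ± 0.29 CPM (SD, n = 3; adjusted p = 0.0022). ANKRD34B was 4.47-fold lower, the glutamate receptor subunit gene GRIN2C 4.18-fold, PLCXD3 3.90-fold, VSTM2B 3.87-fold and the calcium channel gene CACNA1H 3.73-fold. LRRC15 was 3.69-fold lower, the ectonucleotidase gene ENTPD2 3.63-fold, and the muscarinic receptor gene CHRM4 and RTN4RL1 3.56-fold each. Among the 9 rises were C11orf96 at 3.38-fold, HSPA6, an inducible HSP70 gene, at 2.61-fold, PPP1R3C, a glycogen-targeting phosphatase subunit gene, at 2.52-fold, and the ubiquitin ligase gene RNF144B at 2.27-fold. ULBP2, which encodes a ligand of an activating immune receptor, was 2.04-fold higher, CEMIP 1.85-fold, ZNF30 1.75-fold and WNT9A 1.74-fold. The 4 induced genes that were higher were CEMIP, RNF144B, HSPA6 and NHLH2, the last named after its value was seen. By chance 0.15 of the 9 rises would be induced genes. Of the 121 falls also tested in 2023, 42 were induced genes, where 2.05 would overlap by chance.

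The fixed p53 target lists did not move as sets between LLPSEp53_1 and p53, with camera adjusted p from 0.52 to 0.84 with an estimated correlation. Nor did any fixed list pass fry's directional test, with adjusted p from 0.058 to 0.91 for the p53 target lists. Fry's mixed test gave adjusted p of 0.017 for metabolism and autophagy, 0.028 for growth arrest and 0.048 for other targets. It gave 0.11 for DNA repair, 0.12 for apoptosis and 0.14 for feedback. Outside the p53 lists it gave 0.0041 for NF-kB targets and 0.028 for G1/S, heat shock and epithelial-mesenchymal genes. It gave 0.049 for ribosome biogenesis and 0.062 or more for the others. In the growth arrest list, 0 of 16 members were called by edgeR and 1 by DESeq2, with 3 higher adjusted over the list alone, 4 higher and 1 lower at unadjusted p under 0.05, and a median log2 change of 0.03. The apoptosis list (17 measured, median 0.03) and the DNA repair list (8 measured, median 0.09) had 0 members called by edgeR or DESeq2 and 0 adjusted over each list alone. At unadjusted p under 0.05, 1 apoptosis gene was lower and 3 DNA repair genes were higher. The feedback list (7 measured, median -0.0043, with the mean and the test of the opposite sign) had 0 called by either tool and 1 higher adjusted over the list alone and at unadjusted p under 0.05. The metabolism and autophagy list (16 measured, median -0.03, with the mean and the test of the opposite sign) had 0 called by edgeR and 1 by DESeq2, FDXR having the smallest adjusted p in edgeR at 0.085. Of its members 1 was higher adjusted over the list alone and 2 at unadjusted p under 0.05. In the list of other targets, 1 of 52 was called, THBS1 at 1.92-fold lower (1 adjusted over the list alone, median -0.04).

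G1/S genes (median log2 change 0.27, 32 measured), G2/M genes (median 0.23, 32 measured) and ribosome biogenesis genes (median 0.36, 20 measured) lay higher with LLPSEp53_1 at the preset correlation, but with an estimated correlation their adjusted p was 0.43, 0.43 and 0.40. None of these members passed edgeR's adjusted threshold, although 10, 6 and 9 were higher at unadjusted p under 0.05, 1 G1/S gene was called by DESeq2, and 9 ribosome biogenesis genes were higher adjusted over the list alone. Ribosomal protein genes took 4.12% and 3.88% of counts in p53 replicates 1 and 3, and 4.10%, 4.95% and 5.91% in the LLPSEp53_1 libraries. Heat shock genes had 1 of 15 higher, HSPA6 (2 adjusted over the list alone, median 0.20, adjusted p = 0.52 with an estimated correlation). Interferon genes had a median of -0.18 (adjusted p = 0.54 with an estimated correlation), with 0 of 27 called by edgeR or DESeq2, 0 adjusted over the list alone, and 5 lower and 1 higher at unadjusted p under 0.05. The 5 measured markers of other cell types had a median of -1.11 (adjusted p = 0.51 with an estimated correlation) and stayed at or below 2.49 CPM in every library, with 0 called by edgeR or DESeq2, 0 adjusted over the list alone and 3 lower at unadjusted p under 0.05.

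No set call was made between LLPSEp53_1 and p53 for the other 7 lists. In the NF-kB list 1 of 14 members was lower, TNFAIP2 at 2.08-fold (2 lower and 1 higher adjusted over the list alone, median -0.13). The unfolded protein and integrated stress response list (20 measured, median -0.04, with the mean and the test of the opposite sign), NRF2 targets (17 measured, median 0.01), sterol synthesis genes (19 measured, median -0.08), epithelial-mesenchymal genes (18 measured, median -0.21), mitochondrially encoded mRNAs (13 measured, median 0.08) and replication-dependent histones (15 measured, median -0.18) had 0 members called by edgeR and 0 adjusted over each list alone. DESeq2 called 1 of these genes, in the stress response list. At unadjusted p under 0.05 the numbers higher and lower were 1 and 1, 0 and 2, 0 and 3, 2 and 2, 3 and 0, and 0 and 1, in that order.

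All 155 genes had libraries that did not overlap between LLPSEp53_1 and p53 replicates 1 and 3, as did 26.9% of all tested genes where chance gives 20%. The set of induced genes passed camera with an estimated correlation (p = 0.0045; Benjamini-Hochberg over 6 set tests 0.0090), whereas the 5 genes that WT repressed at least 2-fold did not (median 0.10, p = 0.55), with 0 called by edgeR or DESeq2, 0 adjusted over the list alone and 1 higher at unadjusted p under 0.05. The number of genes was unstable. It was 258 with DESeq2, 562 without the count filter (356 lower and 206 higher), 237 with the GC trend removed (added after seeing the data), 94 without the batch term and 64 from these 2 groups alone. Leaving out 1 library gave 28 (p53 replicate 1), 568 (LLPSEp53_1 replicate 1, with 425 lower and 143 higher), 13 (LLPSEp53_1 replicate 2), 71 (LLPSEp53_2 replicate 2) and 0 (p53 replicate 3, with 1634 at unadjusted p under 0.05 and 68 by DESeq2). Without the batch term, which lets p53 replicate 2 enter, the median of the induced genes was -0.82, that of the repressed genes -1.04, that of the growth arrest list -0.41 and that of the stress response list -0.45, while that of sterol synthesis genes was 0.24.

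**Figure D1:**
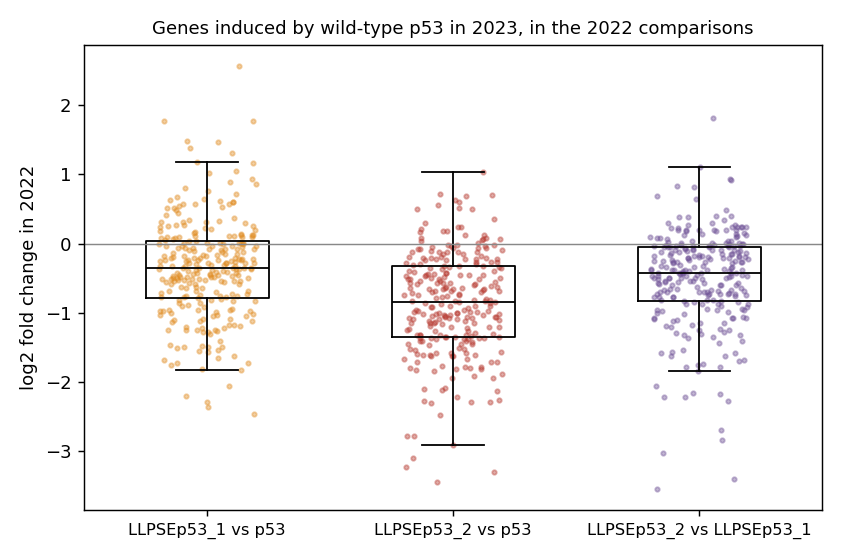
Log2 fold change, in each 2022 comparison, of the 269 genes that WT induced at least 2-fold over Ctrl in 2023. Each point is a gene, boxes show the median and quartiles, whiskers reach the last gene within 1.5 box lengths, and the grey line marks 0; the medians were -0.35, -0.84 and -0.42.

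LLPSEp53_2 differed from p53 in the same direction, in 337 of 17459 genes, of which 319 were lower and 18 higher. That is more genes than with LLPSEp53_1, but without LLPSEp53_1 replicate 1 the order turned, with 491 genes against 568. The median log2 change of the induced genes was -0.84 (quartiles -1.36 and -0.32). Of 269, 242 were below 0, 98 were called lower (165 adjusted over the list alone) and 0 higher by edgeR or DESeq2, with 1 higher adjusted over the list alone and at unadjusted p under 0.05. Without p53 replicate 1, 48 were called lower, and without p53 replicate 3, 49. ARC, an activity-regulated cytoskeletal gene, went from 97.5 ± 5.60 CPM with p53 (SD, n = 2) to 14.2 ± 2.71 CPM (SD, n = 3), 6.88-fold lower (adjusted p = 1.02e-05). FGFR3 was lower by a log2 change of -1.59 and KCNJ12 by -1.71. CDKN1A stood at 261 ± 25.7 CPM (SD, n = 3) and MDM2 at 139 ± 22.9 CPM (SD, n = 3), and neither difference from p53 passed the test (adjusted p = 0.76 and 0.41).

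The polo-like kinase gene PLK5 was 7.53-fold lower, RTN4RL1 6.19-fold, DOC2B 5.57-fold, ANKRD34B 5.00-fold and the chemokine gene CCL2 5.19-fold. Among homeobox genes, UNCX was 5.67-fold lower and LHX3 4.95-fold. The pseudogenes RPL17P18 and RPL37AP1 were each 5.52-fold lower, but they share reads with their parent genes and their values are uncertain. Among the rises, the mitochondrial chaperonin gene HSPE1 was 2.34-fold higher, the iron exporter gene SLC40A1 2.15-fold, HOXA7 1.98-fold, the mitochondrial 12S ribosomal RNA gene MT-RNR1 1.98-fold and CYTOR 1.69-fold. EIF3C, GAGE13, HMGB1P5 and the transfer RNA gene MT-TY also rose, by 3.96, 3.69, 2.15 and 6.30-fold. The first 3 have near-identical copies and the last is shorter than most library fragments, so these values are uncertain.

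**Figure D2:**
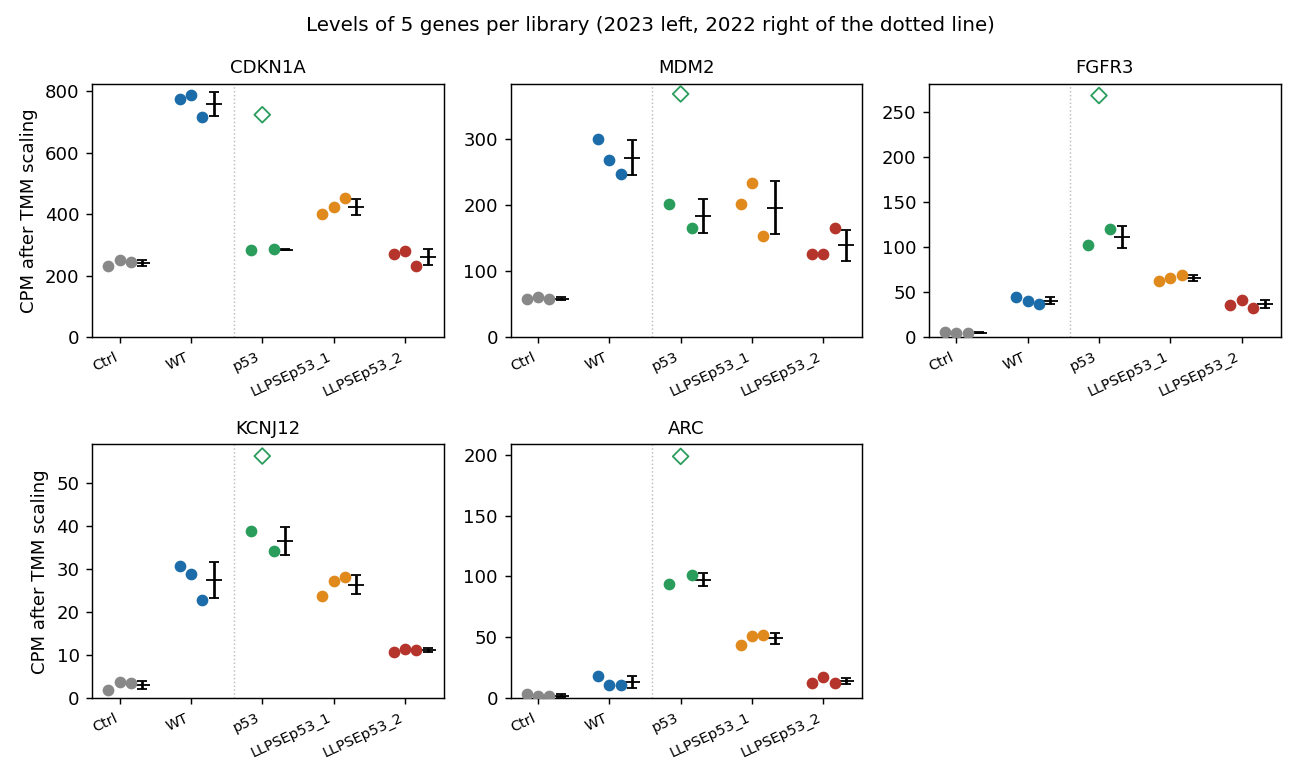
CPM after TMM scaling of CDKN1A, MDM2, FGFR3, KCNJ12 and ARC in each library, on linear axes from 0; libraries of 2023 are left of the dotted line. Filled points are libraries, the open diamond is p53 replicate 2 of the other batch, and bars are the mean and SD of the filled points; ARC lies at 14.2 ± 2.71 CPM with LLPSEp53_2 against 49.1 ± 4.55 CPM with LLPSEp53_1.

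Interferon response genes were the fixed list with the most called members in this comparison. With LLPSEp53_2, 9 of 27 were lower (23 adjusted over the list alone) and the median log2 change was -0.67. IFI44L was 4.57-fold lower, OAS1 2.56-fold, MX1 2.34-fold and IFI6 2.18-fold. With an estimated correlation the list's camera p was 0.0071 and its adjusted p over the lists 0.077. Its adjusted p by fry was 0.012, and that of NF-kB targets and of replication-dependent histones 0.029 and 0.029. In the NF-kB list, 3 of 14 were lower (5 adjusted over the list alone, median -0.26, adjusted p = 0.17 with an estimated correlation), CCL2, TNFAIP2 at 2.58-fold and TRAF1 at 1.72-fold. Replication-dependent histones had 2 of 15 lower (6 adjusted over the list alone, median -0.43, adjusted p = 0.17 with an estimated correlation), H3C2 at 3.38-fold and H4C8 at 1.64-fold, members of multigene families.

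Of the p53 target lists, 4 were lower with LLPSEp53_2 than with p53 at the preset correlation of camera. None held over the lists with an estimated one. Fry, which does not set a list against other genes, gave adjusted p of 1.9e-04 for other targets and 0.037 for feedback. It gave 0.029 for growth arrest and for metabolism and autophagy, 0.054 for apoptosis and 0.22 for DNA repair. In the growth arrest list, 1 of 16 was lower, BTG2 at 2.08-fold (2 adjusted over the list alone, median -0.15, adjusted p = 0.19 with an estimated correlation). In the list of other targets, 2 of 52 were lower, CSF1 at 2.17-fold and FAM13C at 2.13-fold (3 adjusted over the list alone, median -0.12, adjusted p = 0.077 with an estimated correlation). The apoptosis list (17 measured, median -0.20, adjusted p = 0.30 with an estimated correlation) had 0 called by edgeR or DESeq2, 0 adjusted over the list alone and 6 lower at unadjusted p under 0.05. The feedback list (7 measured, median -0.28, adjusted p = 0.22 with an estimated correlation) had 0 called by edgeR and 1 by DESeq2, with 1 lower adjusted over the list alone and 2 at unadjusted p under 0.05. No set call was made for metabolism and autophagy (16 measured, median -0.10, 0 called by edgeR, 1 by DESeq2, 2 lower adjusted over the list alone, 4 lower at unadjusted p under 0.05) or DNA repair (8 measured, median 0.07, 0 called by edgeR, by DESeq2, over the list alone or at unadjusted p under 0.05).

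G1/S genes had 1 of 32 higher, GINS1 at 1.68-fold (2 adjusted over the list alone, median 0.29, adjusted p = 0.17 with an estimated correlation). G2/M genes (32 measured, median 0.21) and ribosome biogenesis genes (20 measured, median 0.23) each had an adjusted p of 0.17 with an estimated correlation, with 0 called by edgeR or DESeq2, 0 adjusted over each list alone, and 6 and 3 higher at unadjusted p under 0.05. The adjusted p by fry was 0.029 for G1/S, ribosome biogenesis and epithelial-mesenchymal genes, and 0.031 for G2/M genes. Ribosomal protein genes took 4.94%, 4.49% and 3.90% of counts in the LLPSEp53_2 libraries. Epithelial-mesenchymal genes (18 measured, median -0.19, adjusted p = 0.19 with an estimated correlation) had 0 called by edgeR and 1 by DESeq2, with 1 lower adjusted over the list alone and 5 at unadjusted p under 0.05. Mitochondrially encoded mRNAs (13 measured, median 0.16, adjusted p = 0.44 with an estimated correlation) had 0 called by edgeR and 1 by DESeq2, with 1 higher adjusted over the list alone and 2 at unadjusted p under 0.05. Markers of other cell types had 1 of 5 lower, COL3A1 (1 adjusted over the list alone, median -0.82, adjusted p = 0.22 with an estimated correlation), at 1.498 ± 1.22 CPM with p53 (SD, n = 2). No set call was made for heat shock genes, of which 1 of 15 was higher, HSPE1 (1 adjusted over the list alone, median 0.19). The stress response list (20 measured, median 0.01), NRF2 targets (17 measured, median 0.05) and sterol synthesis genes (19 measured, median 0.03) had no set call and 0 called by edgeR or DESeq2, 0 adjusted over each list alone, and 2 higher and 1 lower, 2 lower, and 1 higher and 1 lower at unadjusted p under 0.05.

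All 337 genes had libraries that did not overlap between LLPSEp53_2 and p53 replicates 1 and 3, as did 33.1% of all tested genes where chance gives 20%. The induced set passed camera with an estimated correlation (p = 1.0e-04; Benjamini-Hochberg over 6 set tests 6.0e-04). The 5 repressed genes had a median of -0.01, with the test of the opposite sign (p = 0.89 with an estimated correlation), with 0 called by edgeR or DESeq2, over the list alone or at unadjusted p under 0.05. The number of genes was 507 with DESeq2, 823 without the count filter (601 lower and 222 higher), 568 with the GC trend removed (added after seeing the data) and 1040 from these 2 groups alone (753 lower and 287 higher). Leaving out 1 library gave 127 (p53 replicate 1), 93 (p53 replicate 3), 928 (LLPSEp53_1 replicate 3, with 691 lower and 237 higher), 155, 154 and 191 (LLPSEp53_2 replicates 1, 2 and 3). Without the batch term the median of the induced genes was -1.29, that of the repressed genes -1.08 and that of the stress response list -0.53.

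The LLPSEp53 constructs shared many of their differences from p53, with the p53 libraries common to both comparisons. Of the 146 genes lower with LLPSEp53_1 and the 319 lower with LLPSEp53_2, 113 were the same genes, of which 35 were among those induced by WT in 2023; independent lists of these sizes would share 2.67. In 20 simulations all 9 libraries, p53 included, were redrawn around the p53 level with no change between groups. Both comparisons then shared the redrawn p53 libraries. An average of 0 genes were lower in both by edgeR, and 91.8 at unadjusted p under 0.05 where 700 were observed. With no change built in, adjusted calls lie near 0, so that 0 does not measure what the real shared controls add. Of the 9 and 18 rises, 0 were shared by edgeR. Across 17459 genes, which are not independent replicates, the log2 changes of the 2 comparisons had a Pearson r of 0.70 against 0.60 in the simulations, and a covariance of 0.16 against 0.06, a difference of 0.10. The 2 p53 libraries of the shared batch were not split between the comparisons, which would leave 1 for each. Part of the excess of shared genes may come from the shared controls. The simulations leave out real effects, and their genes were drawn independently of each other.

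Set directly against each other, LLPSEp53_2 and LLPSEp53_1 differed in 65 of 17459 genes, 61 lower and 4 higher with LLPSEp53_2. CDKN1A was among them, 1.63-fold lower with LLPSEp53_2 at 261 ± 25.7 CPM against 424 ± 26.1 CPM (SD, n = 3 each; adjusted p = 0.030), while MDM2 at 139 ± 22.9 against 196 ± 40.2 CPM (SD, n = 3 each; adjusted p = 0.46) did not pass the test. The induced genes were lower with LLPSEp53_2 than with LLPSEp53_1 by a median log2 change of -0.42 (quartiles -0.84 and -0.04). Of 269, 217 were below 0, 34 were called lower (98 adjusted over the list alone) and 0 higher by edgeR, with 4 higher by DESeq2, 6 adjusted over the list alone and 7 at unadjusted p under 0.05. Those called lower numbered 14, 17 and 13 without LLPSEp53_2 replicates 1, 2 and 3, 15 without LLPSEp53_1 replicate 2, 52 (with 3 higher) without LLPSEp53_1 replicate 3, 16 with the replicate number as a block and 2 without the batch term. Of the 57 genes called lower that were also tested in 2023, 34 were genes induced by WT, where 0.97 would overlap by chance.

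Among genes with an average log2 CPM of at least 2, pseudogenes aside, the steepest falls from LLPSEp53_1 to LLPSEp53_2 were LHX3 at 8.17-fold, SFRP4, a secreted Wnt antagonist gene, at 4.88-fold, the transcription factor gene SOX7 at 4.50-fold, PLK5 at 4.16-fold and C11orf96 at 3.93-fold. ARC was 3.47-fold lower, at 14.2 ± 2.71 against 49.1 ± 4.55 CPM (SD, n = 3 each), and HSPA6 3.24-fold lower. RPL37AP1, RPL17P18 and RPS2P55, pseudogenes that share reads with their parent genes, were lower by 7.76, 6.94 and 3.31-fold and are uncertain. Among the rises were LRRC15 at 3.91-fold, EIF3C at 3.64-fold and LBH at 1.80-fold.

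By list, interferon genes had 2 of 27 lower with LLPSEp53_2 than with LLPSEp53_1 (20 adjusted over the list alone, median log2 change -0.54, adjusted p = 0.058 with an estimated correlation), IFI6 at 2.29-fold and ISG15 at 1.87-fold. The growth arrest list had 2 of 16 lower (5 adjusted over the list alone, median -0.30, adjusted p = 0.072 with an estimated correlation), CDKN1A and PLK3 at 1.90-fold. PLK3 was also the 1 of 7 feedback genes that was lower (3 adjusted over the list alone, median -0.24, adjusted p = 0.079 with an estimated correlation). In the list of other targets 1 of 52 was lower, FAM13C at 2.14-fold (2 adjusted over the list alone, median -0.11, adjusted p = 0.058 with an estimated correlation). The metabolism and autophagy list (16 measured, median -0.07, adjusted p = 0.079 with an estimated correlation) had 0 called by edgeR and 2 lower by DESeq2, with 5 lower adjusted over the list alone and 6 at unadjusted p under 0.05. The apoptosis list (17 measured, median -0.15, adjusted p = 0.15 with an estimated correlation) had 0 called by edgeR and 1 lower by DESeq2, with 4 lower adjusted over the list alone and 5 at unadjusted p under 0.05. Fry gave adjusted p of 4.5e-04 for other targets, 0.012 for growth arrest and for metabolism and autophagy, and 0.017 for interferon genes. It gave 0.024 for feedback, 0.043 for sterol synthesis, 0.045 for apoptosis, and 0.099 or more for the remaining lists.

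NF-kB targets (14 measured, median -0.28, adjusted p = 0.19 with an estimated correlation) had 0 called by edgeR and 1 by DESeq2, with 1 lower adjusted over the list alone and 5 at unadjusted p under 0.05. Sterol synthesis genes (19 measured, median 0.13, adjusted p = 0.15 with an estimated correlation) and replication-dependent histones (15 measured, median -0.19, adjusted p = 0.31 with an estimated correlation) had 0 called by edgeR or DESeq2 and 0 adjusted over each list alone, with 2 sterol genes higher and 1 histone gene lower at unadjusted p under 0.05. Single members were lower in lists with no set call: HSPA6 among 15 heat shock genes (1 adjusted over the list alone, median 0.02), ATF3 at 1.68-fold among 20 stress response genes (1 adjusted over the list alone, median 0.03), and SNAI2, a repressor of epithelial genes, at 2.93-fold among 18 epithelial-mesenchymal genes (1 adjusted over the list alone, median -0.01). For heat shock and stress response genes the mean and the test were of the opposite sign to the median. DNA repair targets (8 measured, median -0.08) had 0 called by edgeR or DESeq2 and 1 lower adjusted over the list alone, with 1 higher and 1 lower at unadjusted p under 0.05. G1/S genes (32 measured, median 0.02), G2/M genes (32 measured, median 0.01), NRF2 targets (17 measured, median -0.02), ribosome biogenesis genes (20 measured, median -0.08), mitochondrially encoded mRNAs (13 measured, median 0.10) and markers of other cell types (5 measured, median 0.00) had 0 called by edgeR or DESeq2 and 0 adjusted over each list alone. At unadjusted p under 0.05, 1 G2/M gene was higher and 1 mitochondrial mRNA lower. The test had the opposite sign to the median for NRF2 targets and for markers of other cell types, and the mean had for mitochondrial mRNAs.

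All 65 genes had libraries that did not overlap between the LLPSEp53 groups, as did 13% of all tested genes where chance gives 10%. The induced set passed camera with an estimated correlation (p = 5.2e-04; Benjamini-Hochberg over 6 set tests 0.0016). The 5 repressed genes had a median of -0.28 (p = 0.54 with an estimated correlation), with 0 called by edgeR or DESeq2, over the list alone or at unadjusted p under 0.05. The number of genes was 151 with DESeq2, 235 without the count filter, 106 with the GC trend removed (added after seeing the data), 3 without the batch term and 35 from these 2 groups alone. Leaving out 1 library gave 24 (LLPSEp53_1 replicate 2), 198 (LLPSEp53_1 replicate 3), 24, 25 and 21 (LLPSEp53_2 replicates 1, 2 and 3).

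**Figure D3:**
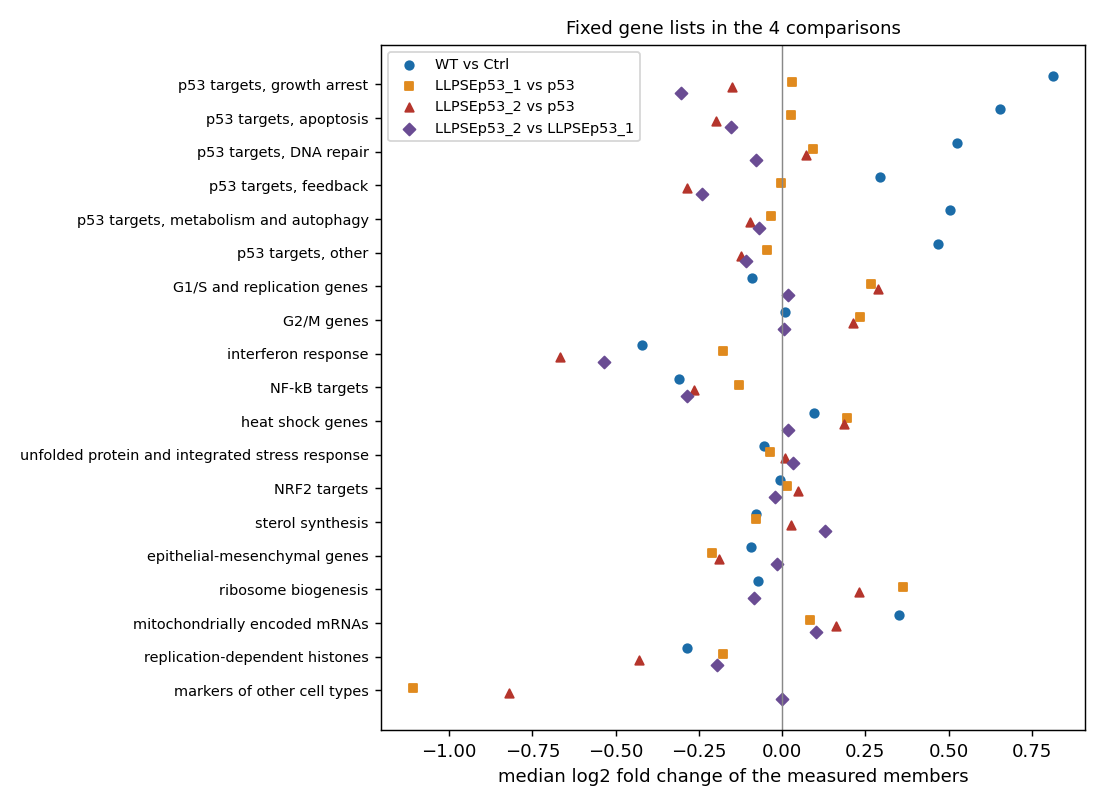
Median log2 fold change of the measured members of each fixed gene list (rows) in the 4 comparisons, 1 symbol per comparison; the grey line marks 0. The 6 lists of p53 targets had medians between 0.29 and 0.82 in WT against Ctrl, while the interferon list had a median of -0.67 in LLPSEp53_2 against p53.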

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

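The tests of GC content were chosen after the results they bear on had been seen.

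The constructs' effects differed from each other. Set directly against each other, LLPSEp53_2 and LLPSEp53_1 differed in 65 genes, and the genes that WT induced in 2023 were lower with LLPSEp53_2 by a median log2 change of -0.4201. Of the 10 splits of these 6 libraries, 1 gave as many genes, the real one, with 2 genes as the highest other; 1 gave as large a median of the induced genes, against a highest other of 0.2182 in size. With 10 splits the share is never under 0.1, too few for a test.

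A difference also stood in the p53 library that the 2022 comparisons leave aside. In p53 replicate 2, of another batch, the genes induced by WT lay above their level in the other p53 libraries by a median log2 difference of 0.999. CDKN1A was at 723 CPM there against 284 and 286 CPM in replicates 1 and 3, MDM2 at 368 against 202 and 165 CPM, and FGFR3 at 268 against 103 and 121 CPM. The batch holds 1 library, so its effect has no replicates. The rise was not confined to induced genes. When this library entered the p53 level, without the batch term, the median of the 5 repressed genes fell as well. It went from 0.0988 to -1.0385 in LLPSEp53_1 against p53 and from -0.0077 to -1.0808 in LLPSEp53_2 against p53. The induced medians went from -0.3472 to -0.8208 and from -0.8416 to -1.2912.

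The genes induced by WT were lower with both constructs than with p53. Bias with GC content as the whole cause is argued against, since the medians with that trend removed were -0.8944 for LLPSEp53_2 and -0.3462 for LLPSEp53_1. As the whole cause, a gradient in ribosomal protein reads is argued against by medians of -0.8172 and -0.2914 with that share as a covariate. With the covariate, 24 of the set were called lower and 2 higher with LLPSEp53_1, against 42 and 4 without it. With LLPSEp53_2, 122 were called lower against 98. A part of the gradient in the LLPSEp53_1 result stays open. Lower activity of the constructs on the induced genes stays open as a hypothesis that may account for their lower levels. Differences in protein amount or in the cultures, which RNA counts do not measure, stay open beside it. Of 10 splits, 1 gave as large a median in each comparison, the real one, with 0.7034 against 0.8416 and 0.2985 against 0.3472 as the highest others in size. Those others keep p53 replicates 1 and 3 together, and the batch term takes up replicate 2, so they partly repeat the real contrast; the splits that part these 2 libraries reached at most 0.2007 and 0.1041. Still, 10 splits are too few for a test.

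The genes lower in WT than in Ctrl were mostly rich in GC. With the GC trend removed, 28 of the 141 were still past the threshold; their median log2 change went from -0.49 to -0.31 and their median SE from 0.117 to 0.104, so smaller changes and not a wider spread ended the calls. A bias with GC content may therefore account for much of this set. As the whole cause it is argued against for the immediate early genes, a list of 24 drawn up after EGR1 and FOSB had been seen: 13 were called lower and 11 of these still were with the trend removed, with a median of -0.67 before and -0.55 after. Over all 24, called or not, the median went from -0.55 to -0.41, so part of the shift may go with GC content, while ARC, EGR2 and ATF3 were higher in WT. A biological cause for the immediate early genes was not tested.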

How the results depend on the processing

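The GC and length offsets were added after seeing the data. The median log2 changes of the genes induced by WT kept their direction under every alternative that was run. They also kept their side of the threshold at the preset correlation of camera. The alternatives were not run with an estimated correlation, so they do not show whether the set p values printed above would hold.

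Counts of genes changed moved by more than 1.5 times under these alternatives. With DESeq2 the numbers were 258 for LLPSEp53_1 against p53, 507 for LLPSEp53_2 against p53 and 151 for LLPSEp53_2 against LLPSEp53_1, and without a filter on low counts 562, 823 and 235, in the same order. With the GC offset they were 237, 568 and 106. From only the groups compared they were 64, 1040 and 35. Without the batch term they were 94 for LLPSEp53_1 against p53 and 3 for LLPSEp53_2 against LLPSEp53_1. No p53 library enters the difference between the constructs, and their induced median hardly moved (-0.4215 against -0.4201). The fall to 3 genes therefore came through the shared estimate of the spread, which p53 replicate 2 then enters. A 2-fold minimum left 285 genes for WT against Ctrl, by its construction. For the remaining moves the cause was not tested.

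Replicate numbers as a block gave 1645 genes for WT against Ctrl (894 higher and 751 lower), 40 and 183 for LLPSEp53_1 and LLPSEp53_2 against p53, and 33 between the constructs. In 2022 no pairing by number was seen. Same-number correlations after removal of group means ranged from -0.385 to 0.181, and different-number ones from -0.198 to 0.358. In 2023 the 3 same-number correlations ranged from 0.021 to 0.247 and the 6 different-number ones from -0.206 to 0.134. The labels do not say what the numbers mark, so a pairing in 2023 stays open.

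Leaving out 1 library at a time gave 356 to 1381 genes for WT against Ctrl, 0 to 568 for LLPSEp53_1 against p53, 93 to 928 for LLPSEp53_2 against p53 and 21 to 198 between the constructs. The lowest of these, 0 by edgeR without p53 replicate 3, stood beside 1634 genes at unadjusted p under 0.05 and 68 by DESeq2; that fit leaves 1 p53 library of the shared batch, assumed to vary like the others.

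The genes repressed by WT passed the threshold of camera in LLPSEp53_1 against p53 when taken as the 200 with the smallest p (median 0.0801) and without p53 replicate 3 (median 0.3544). They passed it in LLPSEp53_2 against p53 without WT replicate 2 (median -0.5186) and without Ctrl replicate 1 (median -0.3242). Between the constructs they passed it without WT replicate 2 (median -0.3115) and without Ctrl replicate 1 (median -0.2491). All of these are at the preset correlation, and leaving out a WT or Ctrl library also changes which genes make up the set. Without 1 library at a time their medians ranged from -0.1936 to 0.3544 in LLPSEp53_1 against p53, from -0.5186 to 0.3943 in LLPSEp53_2 against p53 and from -0.3479 to -0.159 between the constructs. Without the batch term they were -1.0385 in LLPSEp53_1 against p53, against 0.0988. In LLPSEp53_2 against p53 they were -1.0808, against -0.0077. The set passed in neither. Those shifts came with the entry of p53 replicate 2 into the p53 level. Why that library differed was not tested, nor was the cause of the other changes.

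Of the pairs of a list and an alternative, 5 reversed. For mitochondrially encoded mRNAs, WT vs Ctrl, leaving out 1 library at a time gave medians from -0.0508 (without Ctrl replicate 1) to 0.6221 (without Ctrl replicate 3). Without the batch term the medians were -0.4144 for p53 targets, growth arrest, LLPSEp53_1 vs p53, -0.4541 for unfolded protein and integrated stress response, LLPSEp53_1 vs p53, 0.243 for sterol synthesis, LLPSEp53_1 vs p53, and -0.527 for unfolded protein and integrated stress response, LLPSEp53_2 vs p53. The medians without the batch term came with the entry of p53 replicate 2 into the p53 level. Why that library differed was not tested, nor was the cause of the mitochondrial reversal. The other results are counted once per list or gene and alternative, for WT against Ctrl, LLPSEp53_1 and LLPSEp53_2 against p53, and between the constructs. Of 252, 361, 361 and 360 such pairs of a list and an alternative, 9, 14, 24 and 2 lost a call and 5, 11, 9 and 3 gained one. Of 1273, 1765, 1784 and 1688 pairs of a named gene and an alternative, 40, 91, 129 and 93 lost a call and 57, 43, 74 and 42 gained one.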

Other observations

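The test by membership of the target lists was chosen after the result was seen; the tests by level in Ctrl and of the splits were planned.

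Other splits of the libraries were counted for the numbers of genes changed. For WT against Ctrl, 1 of 10 splits gave as many genes as the real 665, and the highest other gave 0 by edgeR (at most 1434 at unadjusted p under 0.05 and 123 by DESeq2 among the other splits). For LLPSEp53_2 against p53, 1 of 10 gave as many as the real 337, and the highest other gave 0 by edgeR (at most 1645 at unadjusted p under 0.05 and 32 by DESeq2). For LLPSEp53_1 against p53, 2 of 10 gave as many as the real 155, and the highest other gave 599, with p53 replicates 1 and 3 and LLPSEp53_1 replicate 1 on one side, which points to a structure of the samples that was not tested. With the batch term p53 replicate 2 does not count, so that split kept the other p53 libraries together, against LLPSEp53_1 replicates 2 and 3. Leaving out LLPSEp53_1 replicate 1 gave 568 genes. With 10 splits the share is never under 0.1, too few for a test.

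Genes induced by WT that lie outside the fixed lists of p53 targets may have fallen further with the constructs than those inside them. With LLPSEp53_2 the median log2 change was -0.96 over 242 genes outside and -0.28 over 26 inside, a difference of -0.682 (permutation p = 0.00017, adjusted 0.00034; -0.32 among genes matched on induction). With LLPSEp53_1 the medians were -0.41 and -0.03, a difference of -0.378 (permutation p = 0.011, adjusted 0.016; -0.37 among matched genes). These are comparisons across genes, which are not independent replicates. The matched differences were not tested. Genes were not matched on their level in Ctrl here, so list membership and that level cannot be told apart.

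A second hypothesis was that induced genes with low levels in Ctrl fell further. Across 268 induced genes, Spearman's rho between the Ctrl level and the log2 change with LLPSEp53_2 was 0.361 (permutation p = 1e-05, the smallest that the permutations can give, adjusted 3e-05; Pearson's r 0.358), so a low level in Ctrl may go with a larger fall. With LLPSEp53_1 rho was 0.014 (permutation p = 0.82, adjusted 0.82, Pearson's r 0.024). The set was chosen by its rise over these same Ctrl levels. Genes were not matched on induction here, so the Ctrl level and the size of induction cannot be told apart.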
